A study of Mus musculus with 8 samples.

How the data were processed

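Gene expression was measured in 8 libraries of primary mouse microglia, 2 for each combination of plasmid and OGD named in the sample titles. Per the labels' protocols, RNA was taken up in TRIzol, poly(A) RNA was selected, stranded libraries with unique molecular identifiers were prepared by the dUTP method, and paired-end reads were sequenced on a NovaSeq. Per the submitters' processing notes, the authors used HISAT, StringTie and edgeR, with no versions given, and the build mm9. The deposited table holds FPKM, fragments per kilobase of a gene model scaled to the mapped fragments, in a column per library. No step of read processing was repeated here.

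The table has 54419 gene models, of which 39015 carry an Ensembl identifier and 15404 a StringTie locus. Of the Ensembl models 37538 (96.2%) have the chromosome, start and end of GENCODE M21, which is built on GRCm38, although the notes name mm9, so coordinates are given as deposited. Names of 2 or more genes are joined in 808 models, and 46 models have no name. All 8 libraries list 29369 models at 0. StringTie spreads fragments over assembled transcripts, so a gene that overlaps another can lose or gain fragments, and a joined model gives 1 value for all its genes.

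No fragment counts were used here, so depth was estimated from the spacing of the smallest values. It came to 15.6 M and 14.1 M fragments in Con, 13.4 M and 17.0 M in PARP14, 15.1 M and 15.0 M in OGD_Con, and 14.7 M and 13.5 M in OGD_PARP14. A model 1 kb long with 1 FPKM then rests on 13 to 17 fragments, and lower values carry more counting error. Between 10446 and 10662 models reached 1 FPKM per library.

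The design fixed before the data were examined named a count model for counts and limma for FPKM, and the branch for FPKM was used. Values were taken as log2(FPKM + 1). Models with a name and at least 1 FPKM in at least 2 of 8 libraries were tested, 11146 in all, of which 712 have joined names. limma (lmFit and eBayes, trend and robust off) fitted 1 model of 4 group means, with 4 residual degrees of freedom. The comparisons were OGD_Con against Con, OGD_PARP14 against PARP14, OGD_PARP14 against OGD_Con, PARP14 against Con and the interaction. A Benjamini-Hochberg adjusted p under 0.05 over all models tested counted as a call. SEs are the moderated ones of limma.

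Of 25 gene lists fixed before the data were examined, those with at least 3 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01. Estimated correlations were an alternative, as was fry, which tests a list against no change rather than against other genes. Ifit1, Cmpk2, Ccl2, Fabp5, Fos and Ier2 matched no deposited name and were not analysed here. Within lists, p-values were also adjusted over the list alone. Counts of list members without OGD_PARP14 replicate 2 are over all genes tested. Genes were named by a rule fixed before the data were examined. It took Parp14 and Lpar5, up to 8 genes per direction with the largest fold change among those called, with both libraries of 1 group above both of the other and a mean of at least 5 FPKM, and list members by p. Predicted genes were left out. Where fewer than 4 passed in a direction, the 4 with the smallest p were given without being called changed. For list members, Parp14 and Lpar5, models under the exact name came first, then models with a joined name, then models matched by transcript. Of several models of the first kind found, the one with the highest mean was used. A joined model with higher values could thus be passed over, and the Gapdh model used held 4.7 to 16.4 FPKM.

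Other settings fixed before the data were examined were a replicate block, no filter and a filter at 5 FPKM, pseudocounts of 0.1 and 5, quantile normalization, median centring, an intensity trend, a minimum log2 fold change of 1, only the libraries compared, and leaving out each library in turn. Fits without OGD_PARP14 replicate 2 (3 residual degrees of freedom) where it is not compared, list tests without each library, and the correlation of both OGD effects were added after the data were seen. The model was tested on simulated data of 11146 genes with the spread of these libraries. In them 100 genes changed by 1 log2 unit and 100 by 2, all drawn from genes above 5 FPKM in Con. Recovery of lower genes was not simulated. The changed genes were drawn at random, and each gene had the same spread in every library. In the data the spread of OGD genes such as Egln3 came largely from OGD_PARP14 replicate 2. The recovery given here need not hold for such genes. For OGD_Con against Con the model recovered 56% of changes of 1 log2 unit and 91% of changes of 2 with all 8 libraries. With the spread of 7 it recovered 89% and 100%. It made 8 and 19 false calls among the unchanged genes, and 0 in an unchanged comparison.

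R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used. Models without a name were left out of the tests, since no gene could be given for them.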

Results

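Microglia, the resident macrophages of the brain, were cultured from C57BL/6 mice at postnatal day 2, and 8 libraries of polyadenylated RNA were sequenced. Per the labels, cells carried a CRISPR-activation plasmid aimed at Parp14 or a control plasmid, and oxygen-glucose deprivation (OGD), a culture model of ischaemia, lasted 6 h. The titles form 4 groups of 2 libraries, named Con, PARP14, OGD_Con and OGD_PARP14. The treatment text describes OGD for every sample, whereas only the titles of OGD_Con and OGD_PARP14 carry it, so the groups followed the titles. Of the gene models in the deposited FPKM table, 11146 were tested, and fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. Group means are given with the SD over 2 libraries. Nothing in the labels says that the libraries of a group came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

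Parp14, which encodes an ADP-ribosyltransferase and is the target of the activation plasmid, was not higher in the libraries labelled PARP14 than in those labelled Con. Its gene model lies on chromosome 16 from 35832874 to 35871544 on the minus strand and is listed as Gm49730, and 3 of the model's 4 transcripts belong to Parp14. It held 61.4 and 50.7 FPKM in the libraries labelled Con and 12.2 and 11.5 FPKM in those labelled PARP14. The libraries labelled OGD_Con held 12.5 and 53.7 FPKM, and those labelled OGD_PARP14 held 55.8 and 54.6 FPKM. The log2 fold change of PARP14 against Con was -2.15 (SE 0.60, limma adjusted p = 1), opposite in sign to an activation, and that of OGD_PARP14 against OGD_Con was 1.05 (SE 0.60, limma adjusted p = 0.571). Groups are therefore named as the libraries are labelled, and every direction drawn between plasmids rests on those labels. Lpar5, a receptor for lysophosphatidic acid on chromosome 6 from 125067920 to 125086047 on the plus strand, shares a gene model with 2010008C14Rik. It held 8.87 and 2.24 FPKM in Con, 2.65 and 7.36 in PARP14, 12.2 and 12.1 in OGD_Con, and 3.66 and 1.58 in OGD_PARP14. OGD_PARP14 against OGD_Con gave -1.92 (SE 0.64, limma adjusted p = 0.571), and no comparison of Lpar5 or Parp14 passed.

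**Figure D1:**
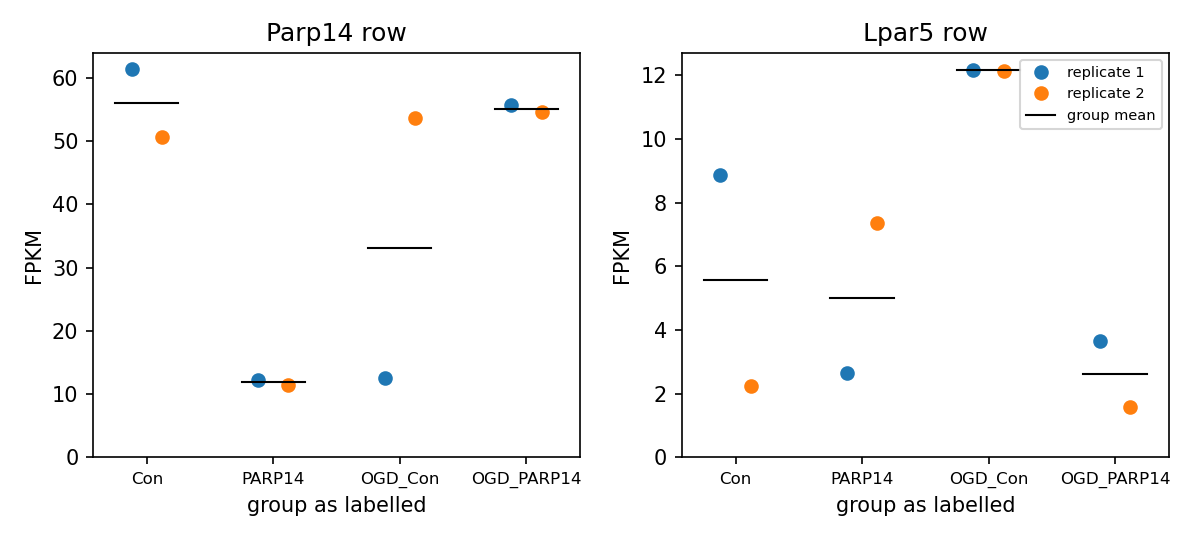
FPKM of Parp14 and of Lpar5 in each of the 8 libraries, grouped by the labels on the horizontal axis. Parp14 lay at 11.5 to 12.5 FPKM in 3 libraries and at 50.7 to 61.4 FPKM in the other 5, and the libraries labelled OGD_Con held 1 of each.

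The library labelled OGD_PARP14 replicate 2 stood apart from the other 7. Its Pearson correlation with each of them over the genes tested was 0.88 to 0.903, while every pair of the others reached at least 0.945. Spp1 (osteopontin, in a joined gene model), Gpnmb and Lgals3, members of the disease-associated microglia list, stood at 5230.85, 1155.87 and 933.63 FPKM there. In the other 7 libraries their highest values were 195.5, 222.7 and 203.7 FPKM. Fcrls, a microglial surface receptor, stood at 74.0 FPKM against at least 1471.9 in the others, and Marco, a scavenger receptor, at 17.4 FPKM against at least 609.8. There 22 of 25 hypoxia and HIF-1 targets lay below each of the other 3 OGD libraries (median log2 difference from their mean -1.95), and 15 of 16 disease-associated microglia genes (1.67) and 16 of 16 cell cycle genes (1.53) lay above each. Of 17 homeostatic microglia genes, 11 lay above each of the other 3 OGD libraries (median of the list 0.59). Fcrls was among the 4 that lay below. Egln3, a HIF-1 target, stood at 1.08 FPKM there against 32.5 to 37.7 in the other OGD libraries. Cxcr4 at 80.1 FPKM and Tnf at 14.6 FPKM lay near the other OGD libraries. Summed FPKM of the astrocyte, neuron and endothelial lists were 4.91, 3.42 and 4.14 in that library, against up to 6.35, 5.12 and 7.53 in the others. The fibroblast and mural list summed to 2.84 FPKM (up to 0.9 elsewhere), the oligodendrocyte lineage list to 31.15 (21.51 to 30.05 elsewhere) and the peripheral leukocyte list to 34.74 (35.5 to 45.91 elsewhere). Because all groups shared one estimate of the spread, each comparison is also given without this library, a fit added after the data were seen.

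**Figure D2:**
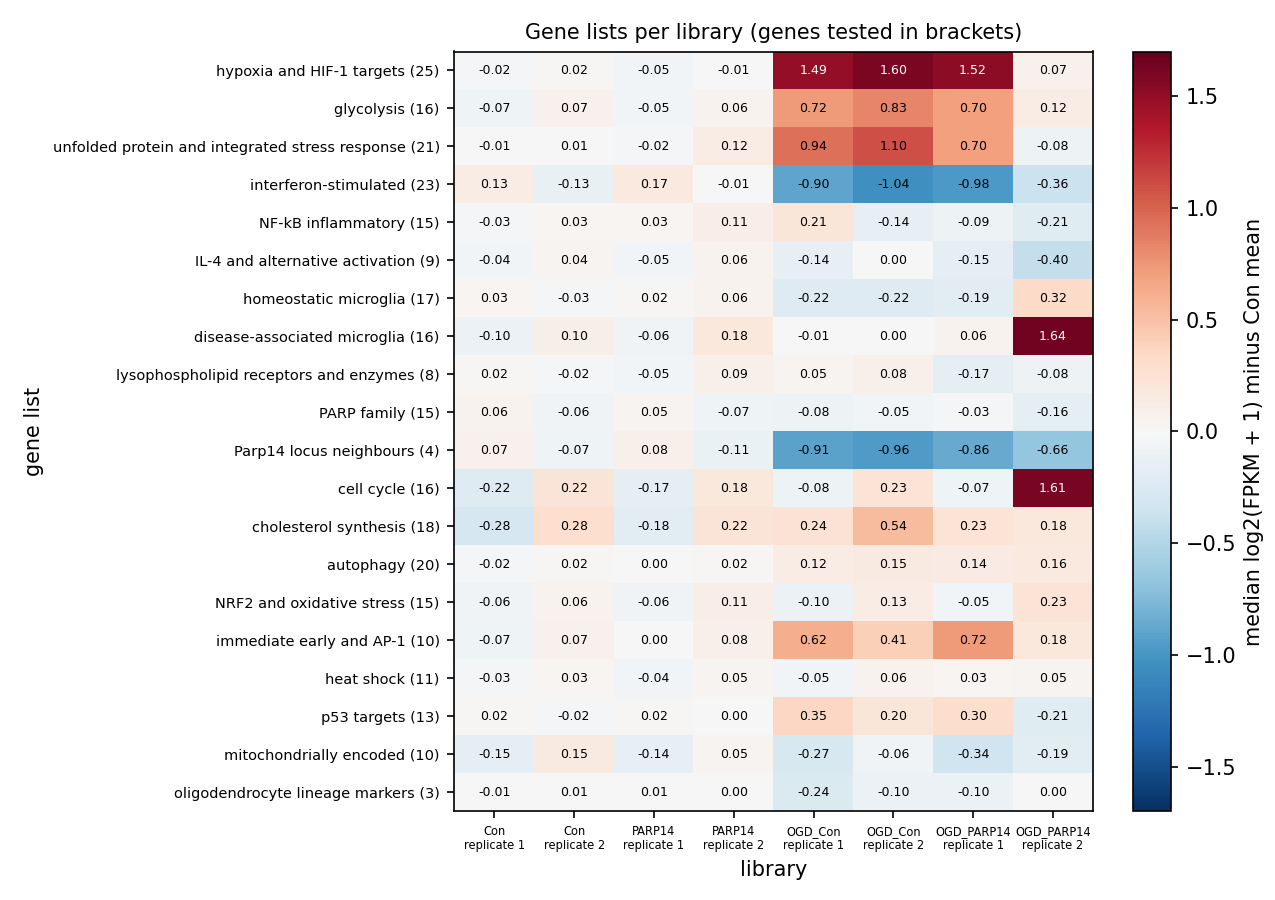
Median over the genes of each list of log2(FPKM + 1) minus the gene's mean in the libraries labelled Con, with lists on the vertical axis and libraries on the horizontal axis. OGD_PARP14 replicate 2 stood at 1.64 for disease-associated microglia and 1.61 for cell cycle genes, above all other libraries, and at 0.07 for hypoxia and HIF-1 targets against 1.49 to 1.60 in the other OGD libraries.

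In cells with the control plasmid, Cxcr4 and Plk2 rose and Tnf and Nfkbia fell with OGD. Cxcr4, the receptor of the chemokine CXCL12, rose from 5.94 ± 2.41 FPKM in Con to 75.5 ± 0.405 in OGD_Con (SD, n = 2; log2 fold change 3.51, SE 0.26, limma adjusted p = 0.0311). Plk2, a stress-induced polo-like kinase and p53 target, rose from 6.03 ± 0.106 to 55.4 ± 0.604 FPKM (3.00, SE 0.21, limma adjusted p = 0.0311). Tnf, the gene of the inflammatory cytokine, went from 61.2 ± 3.62 to 10.3 ± 1.60 FPKM and fell by 2.47 on the log2 scale (SE 0.18, limma adjusted p = 0.0311). Nfkbia, which encodes an inhibitor of NF-kB, went from 87.3 ± 2.77 to 29.6 ± 4.74 FPKM and fell by 1.54 (SE 0.14, limma adjusted p = 0.0394). Pmp22, Tent5c, Gpr157, Lonrf3, the hypoxia list member Mxi1 and the cytokine gene Osm also rose, with log2 fold changes of 1.52 for Osm to 2.09 for Pmp22. Trib1, Trim30c, Pik3ap1, Gna15, Rnf24 and Ampd3 (in a joined gene model) also fell, from -1.94 for Trib1 to -1.05 for Ampd3. In all, limma called 18 genes higher and 12 lower in OGD_Con, and 2144 genes had an unadjusted p under 0.05. No gene passed in limma after leaving out Con replicate 1, Con replicate 2, OGD_Con replicate 1 or OGD_Con replicate 2, when 1042, 1182, 1232 and 944 genes had an unadjusted p under 0.05. Without OGD_PARP14 replicate 2, which this comparison uses only for the spread, limma called 1196 genes higher and 1378 lower, all 30 of the earlier calls among them. With all libraries limma called 74 genes without the filter on low values, 10 with a pseudocount of 0.1 and 49 with an intensity trend, and with only the libraries labelled Con and OGD_Con in the fit it called 1790.

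Genes of the hypoxia response were among the largest changes in that fit of 7 libraries. Egln3, a prolyl hydroxylase induced by HIF-1, rose from 0.799 ± 0.00317 to 35.1 ± 3.67 FPKM (log2 fold change 4.32, SE 0.09, limma adjusted p = 0.000237). With all 8 libraries its adjusted p was 0.156. Bhlhe40 (4.48), H2-K2 (4.21), Ccrl2 (4), Ier3 (3.91), the metallothionein gene Mt2 (3.69), the clock repressor Nr1d1 (3.58) and the angiogenic factor gene Vegfa (3.58) rose as well. Dusp6, which encodes an ERK phosphatase, fell by 3.17, Malat1 (in a joined gene model) by 2.80 and the chemokine gene Ccl7 by 2.32. A short locus that carries the name Ifit2, from 34574936 to 34575434 on the minus strand of chromosome 19, fell by 2.22. None of these 12 gene models passed with all 8 libraries.

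Hypoxia and HIF-1 targets, glycolysis genes and stress-response genes lay higher as lists in OGD_Con, and interferon-stimulated genes lower. Of 25 hypoxia and HIF-1 targets tested, 1 rose among all genes tested (Mxi1) and 17 rose adjusted over the list alone, with a median of 1.54 (camera adjusted p = 5.79e-11 with a preset correlation, adjusted p = 0.423 with an estimated correlation). Without OGD_PARP14 replicate 2, 21 rose and none fell, among them the glucose transporter gene Slc2a1 (2.72), Ak4 (2.92), Ankrd37 (3.05) and Bnip3 (2.89). Of 16 glycolysis genes, 0 passed among all genes and 7 rose adjusted over the list alone (median 0.76, camera adjusted p = 8.88e-07, adjusted p = 0.423 with an estimated correlation). Without that library 13 rose, such as Hk2 (2.42), Pfkl (1.84), Tpi1 (1.49) and Ldha (1.38). Of 21 genes of the unfolded protein and integrated stress response, 0 passed among all genes, and 6 rose and 2 fell adjusted over the list alone (median 1.02, camera adjusted p = 0.00821, adjusted p = 0.538 with an estimated correlation). Without that library 13 rose and 3 fell, with Ppp1r15a (2.84), Trib3 (2.63) and Ddit3 (2.15) among those that rose. All 23 interferon-stimulated genes had a negative fold change, 0 passed among all genes and 17 fell adjusted over the list alone (median -0.89, camera adjusted p = 1.71e-11, adjusted p = 0.423 with an estimated correlation). In this list Ifit2 is the short locus described above. Counts without OGD_PARP14 replicate 2 compare with those among all genes, not with those adjusted over the list alone. Without that library 16 fell, such as Ifit3 (-1.72, in a joined gene model), Isg15 (-1.28), Zbp1 (-1.27) and the RNA sensor gene Ddx58 (-1.18).

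Of 18 cholesterol synthesis genes, 0 passed either way, although all 18 had a positive fold change (median 0.35, camera adjusted p = 0.00037, adjusted p = 0.618 with an estimated correlation). The call was lost without Con replicate 1 (camera adjusted p = 0.132). Of 20 autophagy genes, 0 passed among all genes and 3 rose adjusted over the list alone (median 0.16, camera adjusted p = 0.0177, adjusted p = 0.423 with an estimated correlation). Among 15 PARP family genes Parp11 fell (-0.84, limma adjusted p = 0.0488), and 4 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.126). Of 4 neighbours of Parp14 on chromosome 16, 2 fell adjusted over the list alone (median -0.93, camera adjusted p = 0.075), and without OGD_PARP14 replicate 2 Parp9 and Dtx3l fell and Dirc2 rose. Tiparp, a PARP family gene, rose by 2.14 in that fit. Of 10 immediate early and AP-1 genes, 4 rose and 1 fell adjusted over the list alone (median 0.59, camera adjusted p = 0.0878). Of 13 p53 targets, Plk2 rose, and no other adjusted over the list alone (median 0.29, camera adjusted p = 0.0709, and 0.0286 without the filter on low values). Without OGD_PARP14 replicate 2 the camera adjusted p was 0.0248 for immediate early genes (adjusted p = 0.415 with an estimated correlation) and 0.0343 for p53 targets (adjusted p = 0.52 with an estimated correlation).

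The remaining lists did not pass in OGD_Con against Con. Of 15 NF-kB inflammatory genes, Tnf and Nfkbia fell, and 2 rose and 3 fell adjusted over the list alone. Their median of 0.18 differed in sign from the test, which pointed down (camera adjusted p = 0.775). Of 17 homeostatic microglia genes 0 passed either way (median -0.22, camera adjusted p = 0.703), and without OGD_PARP14 replicate 2 0 rose and 4 fell, such as Tmem119 (-1.06), Mertk and Cx3cr1. Of 16 disease-associated microglia genes 0 passed either way (median -0.03, test up, camera adjusted p = 0.754). The 9 IL-4 and alternative activation genes (median -0.06, test up, camera adjusted p = 0.986), 8 lysophospholipid receptors and enzymes (0.06, camera adjusted p = 0.52), 16 cell cycle genes (0.09, camera adjusted p = 0.462) and 15 NRF2 and oxidative stress genes (0.02, camera adjusted p = 0.52) held 0 calls either way. So did 10 mitochondrially encoded genes (-0.17, camera adjusted p = 0.495). Of 11 heat shock genes 2 fell adjusted over the list alone (median 0.01, test down, camera adjusted p = 0.632), and of 3 oligodendrocyte lineage genes 1 fell, Cnp (median -0.17, camera adjusted p = 0.489). The astrocyte, neuron, endothelial and peripheral leukocyte lists had 1 tested gene each. Aldh1l1 gave 0.04 (limma adjusted p = 0.93), Syn1 -0.04 (0.934), Pecam1 -0.32 (0.855) and Ms4a7, in a joined gene model, 0.09 (0.842). The fibroblast and mural list had 0 tested genes. No list passed with an estimated correlation.

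In cells labelled with the activation plasmid, OGD moved many of the same genes. Between PARP14 and OGD_PARP14, Cxcr4 rose by 3.39 on the log2 scale (limma adjusted p = 0.0248), Plk2 by 2.58 (limma adjusted p = 0.0281), and Tnf fell by 2.17 (limma adjusted p = 0.0293) and Nfkbia by 1.36 (limma adjusted p = 0.0391). Rhov, Pmp22, Tent5c, Mxi1, Dtx4 and Osm also rose, from 1.38 for Osm to 2.44 for Rhov. BE692007 fell by 2.41, and Trim30c, Gna15, Tmem131, Snn and Ythdf2 also fell, from -1.38 for Trim30c to -0.95 for Ythdf2. In all, limma called 14 genes higher and 10 lower, with 1617 at an unadjusted p under 0.05, and the split was 16 and 5 after median centring and 14 and 5 after quantile normalization. With only the libraries labelled PARP14 and OGD_PARP14 in the fit, limma called 0 (700 at an unadjusted p under 0.05). Of the genes called, 11 were raised and 6 lowered in both arms (0.02 and 0.01 by chance), and none went opposite ways. By chance here means with independent calls. Both comparisons share the spread of each gene, so genes with a low spread pass in both more readily. Such values, here and below, can therefore be too low. Without PARP14 replicate 1 or PARP14 replicate 2 limma called 0 genes (783 and 846 at an unadjusted p under 0.05). Without OGD_PARP14 replicate 1, which leaves the library that stood apart, limma called 3497, and without OGD_PARP14 replicate 2 it called 618 higher and 576 lower. In that last fit Egln3 (4.33), Bhlhe40 (4.12), H2-K2 (4.11), Ccrl2 (3.97), Ier3 (3.59) and the growth factor gene Gdf15 (3.39) rose. Malat1 (-3.30, in a joined gene model), the short locus named Ifit2 (-2.96) and Dusp6 (-2.93) fell. The calls of both arms then shared 557 raised and 516 lowered genes (66.31 and 71.21 by chance), and 8 went opposite ways.

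Of the lists, hypoxia and HIF-1 targets (median 0.70, camera adjusted p = 7.48e-07) and glycolysis genes (0.46, camera adjusted p = 4.65e-05) were higher in OGD_PARP14 than in PARP14. For both the adjusted p was 0.57 with an estimated correlation. In each list 1 gene rose adjusted over the list alone with all libraries. Without OGD_PARP14 replicate 2 the medians were 1.69 and 0.72. Both calls were lost without OGD_PARP14 replicate 1 (camera adjusted p = 0.541 each). Interferon-stimulated genes were lower (median -0.82, camera adjusted p = 9.73e-10, adjusted p = 0.57 with an estimated correlation), with 12 of 23 lower adjusted over the list alone. Without OGD_PARP14 replicate 2 their median was -0.94. Autophagy genes were higher (median 0.23, camera adjusted p = 0.00344, adjusted p = 0.463 with an estimated correlation), which was lost without OGD_PARP14 replicate 1 (camera adjusted p = 0.0743), and without OGD_PARP14 replicate 2 the median was 0.12. Disease-associated microglia (median 0.86, camera adjusted p = 4.65e-05) and cell cycle genes (0.80, camera adjusted p = 2.81e-05) were higher, with an adjusted p of 0.57 each with an estimated correlation. Cholesterol synthesis genes were higher as well (0.17, camera adjusted p = 0.0339, adjusted p = 0.715 with an estimated correlation). Without OGD_PARP14 replicate 2 the medians of these 3 lists were 0.06, -0.11 and 0.16, so that of cholesterol genes barely moved. These 3 calls were lost without OGD_PARP14 replicate 2 (camera adjusted p = 0.945, 0.986 and 0.136). That of cholesterol was also lost without OGD_PARP14 replicate 1 (0.433), PARP14 replicate 1 (0.657) and the filter on low values (0.128). Without that filter, and with the preset correlation only, the fibroblast and mural list (camera adjusted p = 0.0413) pointed up and the neighbours of Parp14 (camera adjusted p = 0.0413) down. Without OGD_PARP14 replicate 2, 3 further lists passed. They were the unfolded protein and integrated stress response (camera adjusted p = 0.000136, adjusted p = 0.38 with an estimated correlation), where 10 of 21 rose, immediate early and AP-1 genes (camera adjusted p = 0.02, adjusted p = 0.38 with an estimated correlation), where 3 of 10 rose, and p53 targets (camera adjusted p = 0.0453, adjusted p = 0.495 with an estimated correlation), where 4 of 13 rose.

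**Figure D3:**
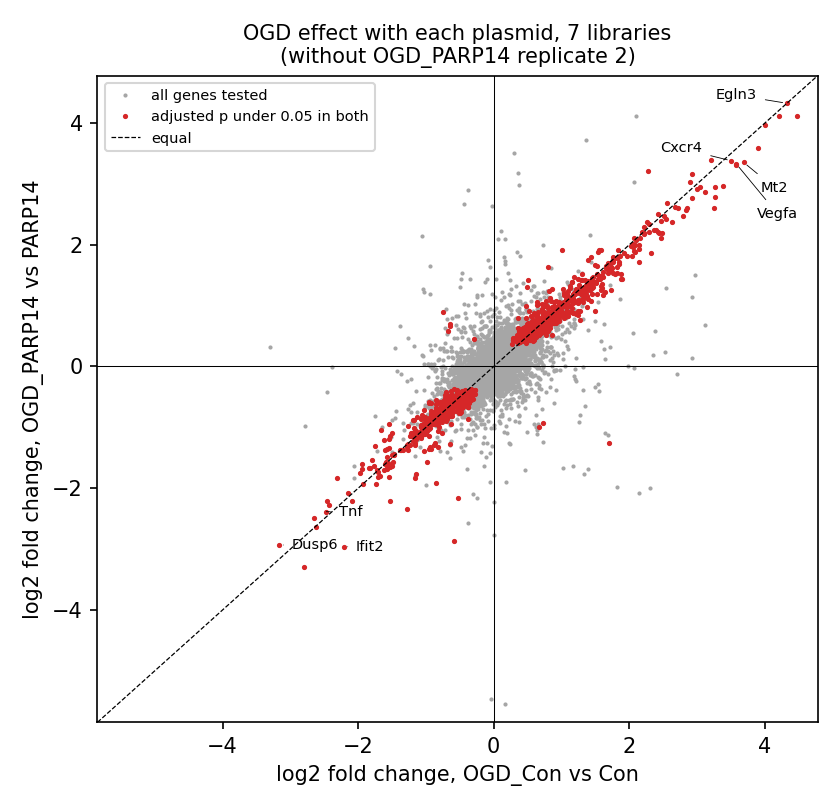
Log2 fold change of OGD_Con against Con on the horizontal axis and of OGD_PARP14 against PARP14 on the vertical axis, without OGD_PARP14 replicate 2, with 1 point per gene tested. The fold changes correlated across genes (Pearson 0.77).

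Between the plasmids under OGD no gene passed with all 8 libraries. Under OGD, BE692007 went from 12.9 ± 0.104 FPKM in OGD_Con to 2.81 ± 0.957 in OGD_PARP14 (log2 fold change -1.89, SE 0.19, limma adjusted p = 0.195). Flvcr1, a heme exporter gene, went from 3.74 ± 0.288 to 12.7 ± 3.66 FPKM (1.5, SE 0.19, limma adjusted p = 0.471). Pgam5, which encodes a mitochondrial phosphatase, went from 6.80 ± 0.27 to 12.9 ± 0.123 FPKM (0.83, SE 0.10, limma adjusted p = 0.471), and the shelterin gene Pot1b gave 0.73 (limma adjusted p = 0.571). Csf2rb (0.79, in a joined gene model), Rps2-ps13 (-0.75) and the autophagy gene Atg14 (-0.95) did not pass either (limma adjusted p = 0.571 each). A short locus that carries the name Wdpcp was listed at 0 in both libraries labelled OGD_PARP14 and at 7.39 and 6.01 FPKM in OGD_Con. In limma 0 genes passed, or 1 after quantile normalization or median centring, and 387 had an unadjusted p under 0.05. Leaving out OGD_Con replicate 1 or OGD_Con replicate 2 also gave 0 (252 and 163 at an unadjusted p under 0.05). Without OGD_PARP14 replicate 1, which leaves the library that stood apart, limma called 4661, and without OGD_PARP14 replicate 2 it called 7 higher and 4 lower. The genes higher in that fit included Abl2 (1.51), Flvcr1 (1.23) and Zfp12 (1.20), and those lower included BE692007 (-1.63) and Golph3l (-1.45, in a joined gene model). Zfp12 was chosen after its values were seen. The library left out lay on the other side of OGD_Con for Abl2 (1.78 FPKM, against 2.29 and 2.35 in OGD_Con and 8.45 in OGD_PARP14 replicate 1) and Golph3l (17.87 FPKM, against 16.73, 15.95 and 5.34). Of the gene models that carry the name Lcor, 1 was also called lower there, listed at 0 in OGD_PARP14 replicate 1, at 38.23 FPKM in OGD_PARP14 replicate 2 and at 59.85 and 56.22 in OGD_Con. A neighbouring Lcor model held 50.63 FPKM in OGD_PARP14 replicate 1, and 0 and 56.33 FPKM in OGD_Con.

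Of the lists, 5 passed between the plasmids under OGD, with 0 members past the threshold among all genes and 0 adjusted over the list alone. Hypoxia and HIF-1 targets were lower in OGD_PARP14 (median -1, camera adjusted p = 0.000423). Disease-associated microglia (0.88, camera adjusted p = 6.92e-06), cell cycle (0.67, camera adjusted p = 0.000114), interferon-stimulated (0.24, camera adjusted p = 0.000542) and homeostatic microglia genes (0.40, camera adjusted p = 0.0256) were higher. For each the adjusted p was 0.805 with an estimated correlation. All 5 calls were lost without OGD_PARP14 replicate 2, when the camera adjusted p was 0.589 for hypoxia and for interferon-stimulated genes, 0.679 for disease-associated and 0.256 for homeostatic microglia. Cell cycle genes gave 0.256 there and pointed down. The homeostatic call was also lost without OGD_Con replicate 2 (0.0543), OGD_PARP14 replicate 1 (0.104) and the filter on low values (0.0581), and the interferon call without OGD_Con replicate 2 (0.0899). Without the filter, and with the preset correlation only, the fibroblast and mural list pointed up (camera adjusted p = 0.0381). None of its genes had passed the filter. The unfolded protein and integrated stress response list pointed down in that setting (camera adjusted p = 0.0435).

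Without OGD, the plasmids differed in a single gene. Gm6793, a predicted gene named here after its values were seen, held 57.0 and 57.7 FPKM in Con and 6.01 and 5.37 in PARP14 (log2 fold change -3.13, SE 0.14, limma adjusted p = 0.00494). The transcripts next in rank did not pass. Cox4i1, which encodes a subunit of cytochrome c oxidase, went from 142 ± 2.45 to 281 ± 9.69 FPKM (SD, n = 2; 0.97, SE 0.18, limma adjusted p = 1). Pgam5 went from 7.57 ± 0.213 to 12.9 ± 0.698 FPKM (0.70, SE 0.10, limma adjusted p = 0.806), and Cir1 gave 0.82 (limma adjusted p = 1). The joined gene model of Sirt7 and Mafg gave -1.28 (limma adjusted p = 0.079), Tmem168 -1.08, Pot1b -0.67 and Snrnp70 -0.54 (limma adjusted p = 1 for these 3). A short locus that carries the name Elmo1 was listed at 0 in both Con libraries and at 6.06 and 5.6 FPKM in PARP14. In limma 0 genes were higher and 1 lower, with 110 at an unadjusted p under 0.05, and 2 passed without the filter on low values or with a pseudocount of 5, and 5 with only the libraries labelled Con and PARP14 in the fit. Without Con replicate 1, Con replicate 2, PARP14 replicate 1 or PARP14 replicate 2 limma called 0 (147, 111, 122 and 131 at an unadjusted p under 0.05). Without OGD_PARP14 replicate 2 it called 3 higher and 3 lower, with Golph3l (1.51, in a joined gene model) among the higher and Sirt7 with Mafg and Tmem168 among the lower.

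Interferon-stimulated genes (median 0.08) and homeostatic microglia genes (0.04) were higher as lists in PARP14 than in Con, each at a camera adjusted p of 0.0319, with 0 members past the threshold and 0 adjusted over the list alone. With an estimated correlation the adjusted p was 0.924 and 0.673. Leaving out OGD_PARP14 replicate 2, which is in neither group, left the medians at 0.08 and 0.04 and changed only the spread. The interferon call was lost without Con replicate 2 (camera adjusted p = 0.648, pointing down), PARP14 replicate 1 (0.941), OGD_PARP14 replicate 2 (0.0544) and the filter on low values (0.157). The homeostatic call was lost without Con replicate 2 (0.31), PARP14 replicate 1 (0.175), PARP14 replicate 2 (0.109), OGD_PARP14 replicate 2 (0.104) and the filter on low values (0.518).

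The plasmid effect differed between OGD and no OGD for Gm6793 alone. It held 72.2 and 69.0 FPKM in OGD_Con and 75.0 and 60.5 in OGD_PARP14, so that the interaction was 3.06 (SE 0.19, limma adjusted p = 0.0432), with 211 genes at an unadjusted p under 0.05. Pot1b (1.40) and the joined gene model of Sirt7 and Mafg (1.32) did not pass (limma adjusted p = 0.348 each), nor did BE692007 (-1.88) and Cox4i1 (-1.86, limma adjusted p = 0.599 each). Parp14 itself gave 3.19 (SE 0.84, limma adjusted p = 0.824). Limma called 0 genes after leaving out Con replicate 1 (169 at an unadjusted p under 0.05), Con replicate 2 (169), PARP14 replicate 1 (162), PARP14 replicate 2 (182), OGD_Con replicate 1 (171) or OGD_Con replicate 2 (148). It called 3295 without OGD_PARP14 replicate 1 and 9 without OGD_PARP14 replicate 2. With all libraries it also called 0 without the filter on low values, with a pseudocount of 0.1 and with an intensity trend (833, 223 and 213 at an unadjusted p under 0.05). Hypoxia and HIF-1 targets had a lower interaction than other genes (camera adjusted p = 0.00563), and disease-associated microglia (camera adjusted p = 0.000583) and cell cycle genes (camera adjusted p = 0.00238) a higher one. For each the adjusted p was 0.752 with an estimated correlation, and without OGD_PARP14 replicate 2 the camera adjusted p was 0.991, 0.979 and 0.243, with disease-associated microglia and cell cycle genes then pointing down.

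Fold changes of whole transcriptomes were compared across genes, which are not independent replicates. The plasmid effects with and without OGD had a Pearson correlation of 0.01 over the genes tested. The OGD effects of both arms correlated at 0.49 with all libraries and at 0.77 without OGD_PARP14 replicate 2. The plasmid effect under OGD against the OGD effect in control cells gave -0.45, but both hold the libraries labelled OGD_Con with opposite sign. Simulated groups without any change gave -0.50 (-0.56 to -0.45 over 100 draws). The simulation gave every group the same spread per gene, which takes in the distance of OGD_PARP14 replicate 2 from replicate 1. With all libraries it therefore cannot tell how much of -0.45 the shared libraries bring. The covariance was -0.093 against -0.061 simulated. Without OGD_PARP14 replicate 2 the correlation was -0.20 against -0.40 simulated, and both covariances were -0.025. Of the genes called in that fit, 1 was raised by OGD and lower with the activation plasmid under OGD, and 3 were lowered and higher (0.43 and 0.87 by chance). Part of any excess may come from the shared libraries and the shared spread.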

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

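All tests of explanations below were chosen after the result was seen, except that of fragments moved to a neighbouring gene model. Gm6793 was flagged because its plasmid effect differed between OGD and no OGD (interaction 3.06 on the log2 scale). Gene models without a name, which no comparison used, held 3.1% of the summed FPKM in OGD_PARP14 replicate 2, against 0.18% to 0.25% in the other 7 libraries, and were flagged as a signal in data left out of the comparisons.

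OGD_PARP14 replicate 2 had low hypoxia and HIF-1 targets, high disease-associated microglia and cell cycle genes and high noncoding RNA such as Rn7sk, chosen after its values were seen (128.2 FPKM against at most 3.7 elsewhere). Dilution by ribosomal or unnamed RNA would move all genes alike, but the hypoxia median less that of all genes was -1.85, against -0.07 to 0.11 for the other OGD libraries, and the highest sum of the astrocyte, neuron, stromal and vascular marker lists was 4.91 FPKM. Cells like those labelled PARP14 that received no OGD do not account for it. Of 401 OGD genes 127 reached 0.5 of the OGD change there, against at most 13 in those libraries. Still, 28 moved as far the other way, and only 66 of 266 raised genes reached 0.5 (median share 0.08). A weaker or shorter OGD as the whole cause was taken to give values between no OGD and OGD. Yet 74.4% of 328 genes at least 4-fold away lay over 1 log2 unit outside the range of the other 7 libraries. That argument holds only if genes do not pass beyond both levels during OGD, which was not tested. The activation plasmid is the biological explanation the design names. Over the 339 genes far from OGD_Con in this library, replicate 1 moved the same way by a median of 0.04 log2 units against 2.73. A plasmid effect shared by both replicates thus does not account for it. An effect in replicate 2 alone cannot be excluded, since the test takes replicate 1 to carry the same effect. Another microglia or macrophage population, with full, weaker or no OGD, and a sample from outside the series were not tested and stay open.

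Parp14 and 24 other gene models of 3957 sat at 1 of 2 levels within a group, such as Junb at 0.65 and 56.72 FPKM in Con, and Pcbp1 at 92.67 and 0.97. Gene models that overlap another or join gene names made up 20% of them against 21% of the others (Fisher's exact p = 1). A model with transcripts of different genes under 1 name, such as that of Parp14, did not count as joined. An opposed neighbour within 20 kb stood beside 0% of them, against 1.8% at random. Overlaps, joined names and such neighbours thus do not account for them as a set. Of 2 neighbouring Lcor models, though, 1 stood at 0 and the other at 50.63 FPKM in OGD_PARP14 replicate 1. For Parp14, a swap of the labels Con and PARP14, which leaves the split within OGD_Con untouched, was not tested and stays open. So does the assignment of fragments between copies of a gene in the genome and between assembled transcripts, also for Gm6793. No biological explanation was tested, since libraries of a group share plasmid and treatment.

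Some genes differed with the replicate number in all of Con, PARP14 and OGD_Con, such as Chil3 at 16.23, 16.66 and 16.45 FPKM in the libraries numbered 1 and 128.88, 137.05 and 117.76 in those numbered 2. A number that marks a shared culture or experiment would part more genes this way than other pairings do, and 12 of 3957 gene models were parted by at least 0.5 log2 units against at most 4 in another pairing. OGD_PARP14 replicate 1, not used to pick them, lay nearer the libraries numbered 1 for 8 of them, such as Chil3 (17.46 FPKM) and Marco (666.64), and nearer those numbered 2 for 4, such as Spcs3 (12.28), while median log2 differences from Con were lower in the libraries numbered 1 for cell cycle genes (-0.22, -0.17 and -0.08 against 0.22, 0.18 and 0.23) and cholesterol synthesis genes (-0.28, -0.18 and 0.24 against 0.28, 0.22 and 0.54). The labels do not say what the number means and the 3 pairs leave only 3 other pairings, so a shared culture and chance cannot be told apart for these 12. For this pattern too, no biological explanation was tested.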

How the results depend on the processing

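Fits without OGD_PARP14 replicate 2 where it is not compared, list tests without it or without each library in turn and the correlation of both OGD effects were chosen after the data were seen. Results are given in the order OGD_Con against Con, OGD_PARP14 against PARP14, OGD_PARP14 against OGD_Con, PARP14 against Con and interaction, where the main counts of called genes were 30, 24, 0, 1 and 1. Leaving out each library gave 0 to 2574, 0 to 3497, 0 to 4661, 0 to 6 and 0 to 3295 genes. An arm left with 1 library is assumed there to vary like the other groups. The replicate block gave 0, 1, 0, 1 and 0 genes, and with OGD_PARP14 replicate 2 left out as well 2618, 1040, 1, 4 and 7, and it left the counts of called gene lists as they were. The replicate numbers were not taken as pairs, since the labels do not say what they mark. Deviations of libraries with the same number also correlated at only 0.01 to 0.12 between groups. Among Con, PARP14 and OGD_Con the values were 0.09 to 0.12, and the lower ones involve OGD_PARP14, with the library that stood apart. Still, 8 of 8 libraries correlated best with their own number, as follows where all these values are positive. Without the filter the counts were 74 for OGD_Con against Con, 2 for PARP14 against Con and 0 for the interaction. A pseudocount of 0.1 gave 10 for OGD_Con against Con and 0 for the interaction, and a pseudocount of 5 gave 2 for PARP14 against Con. The intensity trend gave 49 for OGD_Con against Con and 0 for the interaction. Quantile normalization and median centring each gave 1 for OGD_PARP14 against OGD_Con. Fitting only the 2 groups compared gave 1790 for OGD_Con against Con, 0 for OGD_PARP14 against PARP14 and 5 for PARP14 against Con. Of the gene lists, 6, 7, 5, 2 and 3 were called, and 0 in every comparison with an estimated correlation, with or without OGD_PARP14 replicate 2. With fry it was 4, 5, 0, 0 and 0, and 12, 11, 0, 0 and 0 with OGD_PARP14 replicate 2 left out, and without the filter 0 for PARP14 against Con. With all libraries fry called the interferon-stimulated, autophagy and PARP family lists and the neighbours of Parp14 in both OGD comparisons. It also called NF-kB inflammatory genes in OGD_PARP14 against PARP14. Hypoxia and HIF-1 targets (fry adjusted p = 0.0884 and 0.359) and glycolysis genes (0.073 and 0.312) did not pass with fry in either. Without the filter the cholesterol call of OGD_PARP14 against PARP14 (camera adjusted p = 0.128) and the homeostatic call of OGD_PARP14 against OGD_Con (0.0581) were lost, and the fibroblast and mural list was called up in both (0.0413 and 0.0381). Camera results without the filter are given with the preset correlation only. Leaving out each library gave 6 to 9, 3 to 7, 0 to 7, 0 to 4 and 0 to 6 lists. The correlation of plasmid effects, 0.01, was near 0 throughout, at 0 without Con replicate 2 or OGD_PARP14 replicate 1, -0.02 without PARP14 replicate 2, and from -0.02 to 0.03 over all libraries left out. The plasmid effect against the OGD effect ranged from -0.54 to -0.20, and the OGD effects of both arms from 0.12 to 0.77. Among named genes 3744 values kept their side of the threshold, 226 passed only under the alternative, 203 no longer passed and 0 reversed. A reversal was counted only for genes called in the main fit or in the alternative. Changes of sign in genes called in neither were not counted. The cause was not tested, except that fits without OGD_PARP14 replicate 2 leave its distance from replicate 1 out of the shared spread. An estimated depth of 13.4 M to 17.0 M fragments limits low genes most.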

Other observations

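Ribosomal protein genes and macrophage genes outside the lists also set OGD_PARP14 replicate 2 apart, and were chosen after their values were seen. Of 58 ribosomal protein gene models 53 lay below all other 7 libraries there, with a median log2 difference of -0.9. Folr2, a folate receptor of tissue macrophages, stood at 221 FPKM against 12.5 to 19.5 in the others, and Mmp12, a macrophage elastase, at 172.5 FPKM against 8.6 to 18.5. Adgre1, which encodes F4/80, stood at 480.17 FPKM against at least 1340.4.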
